A study of Homo sapiens with 14 samples.

How the data were processed

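Gene expression was measured in 14 small regions of human breast cancer tissue. Each region was 40 µm in size and was picked mechanically from a tissue section 5 µm thick, per the labels' protocols. Poly(A) RNA was captured on oligo(dT) beads and amplified as full-length cDNA with the SMART-Seq v4 low-input kit before sequencing, per the labels' protocols. The kit adds no molecular identifiers, so counts include PCR copies, and intervals and floors given for counts cover counting error only. The design text calls the sections fresh frozen while the series title speaks of fixed tissue, and which of these applied to the 14 regions is not given in the sources used here.

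The authors deposited a table of whole-number counts for 58735 Ensembl genes in the 14 regions, with no normalization applied. HISAT2, Salmon and the builds GRCh38 and hg38 are named in the submitters' processing notes, without versions and without saying which tool made the counts. All 58735 gene IDs of the table are in GENCODE release 29, and 58207 of them had a symbol in the gene name table. Positions are GRCh38, 1-based, from that annotation. The counting rule for reads shared between similar genes is not given in the sources used here, so values of immunoglobulin, T cell receptor, HLA, keratin, ribosomal protein and mitochondrially encoded genes, and of CD24, HSP90AA1, HSPB1 and LDHA, are uncertain where copies or pseudogenes share reads.

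The labels place 4 regions in the T cell type, 5 in the TIL type, which they describe as holding tumor and T cells, and 5 in the Tumor type. The number of donors and sections is not stated, and neither is the marker or morphology by which regions were chosen. The region was therefore the unit of every test, p-values measure the spread between regions only, and they are too small if regions share a donor. As a screen for a library deposited more than once, replicates were compared by a chi-square of their counts over genes. The lowest value per degree of freedom within a type was 4.95, between Tumor regions 4 and 5, so no region was counted as a repeat of another. The value says nothing more of how alike regions are, since separate regions differ by more than counting noise.

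Total counts ran from 67449 to 404365 per region, with a median of 148705. A gene with 0 counts in 1 region could lie at up to 9.28 CPM in Tumor region 3 and up to 47.9 CPM in Tumor region 5, the extremes after TMM scaling, taking 3 counts as the limit. Over a whole group the limit of 3 counts was 5.53 CPM for T cell, 4.21 CPM for TIL and 3.22 CPM for Tumor regions. Folds against a group without counts set the other group's pooled counts per TMM-scaled library, not its mean CPM, against these group floors and are written "at least". Where a group held 1 to 3 counts, the ratio of the pooled counts is given with its exact 95% interval. A share of counts in a single region is given with its exact Clopper-Pearson 95% interval.

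Counts were tested with edgeR 4.0.16 in R 4.3.3, using library sizes summed over all genes, TMM scaling, the filterByExpr filter by group with a minimum count of 10, and quasi-likelihood F tests. All 14 regions entered 1 fit with 3 groups. Of 20057 genes with at least 1 count, 4019 passed the filter. The common biological coefficient of variation was 1.26. Adjusted p-values are Benjamini-Hochberg over the 4019 genes with a threshold of 0.05, and standard errors of log2 fold changes were taken as the fold change divided by the square root of F. Normalised values are CPM over TMM-scaled libraries, as mean ± SD over regions.

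Gene lists for cell types, tumor subtype and cell state, 31 in all with 439 members, were fixed before the data were examined. Each list with at least 3 tested genes was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list. Camera asks whether a list moved relative to the other genes. Members past the threshold were counted over all genes tested and adjusted over the list alone. A score per region was the mean of log2(CPM + 1) over detected members, compared between groups by an exact two-sided permutation test and adjusted over 93 tests. Depth measures were compared in the same way and adjusted over 21 tests. The smallest exact p was 0.0159 for comparisons with the T cell regions and 0.00794 for TIL against Tumor. Similarity between regions was the Spearman correlation of log2(CPM + 1) over the 4019 genes, with 100000 permutations of the region labels for the difference within and between groups.

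Genes named from a comparison followed a rule fixed before the data were examined: the 10 higher and 10 lower genes with the smallest p, up to 4 members of each described list with the smallest p, and ERBB2, ESR1, PTPRC, CD3E, MS4A1 and KRT19 whatever their values. A subset of these is given here, and the result of 1 gene is not reported here. Genes that show a donor's sex were left out.

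The procedure was tested on simulated counts drawn from the real means and library sizes. At a log2 change of 4, 31.3% of changed genes were recovered for T cell against Tumor, 43.3% for TIL against Tumor and 20.9% for T cell against TIL, each over 4019 genes. Recovery of raised and lowered genes was 54.5% and 8.82%, 69.7% and 17.6%, and 39.4% and 2.94% in the same order. At a log2 change of 2 the values were 0%, 1.52% and 1.52%, so that 4-fold differences were rarely detectable in these comparisons. False calls were 6 of 64, 5 of 87 and 1 of 57 in the same order. Camera called 6 of 200 unchanged simulated lists. Genes were simulated independently of each other, so this count cannot show how often camera falsely calls lists whose members vary together. Among the real lists, the estimated correlation was 0.435 for fibroblast and matrix genes in T cell against Tumor regions, above the preset 0.01.

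Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom with quality weights, relative log expression scaling, no scaling, no filter, a filter of 10 counts in 4 regions, fits of only the groups compared, the region number as a block, the number of genes detected as a covariate, libraries thinned to 67449 counts, removal of mitochondrial genes and ribosomal RNA, robust empirical Bayes, other pseudocounts and summaries, and leaving out each region. One alternative, without Tumor regions 1 and 2, was added after the data were seen because they lay apart from the other Tumor regions.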

Results

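Poly(A) RNA from 14 micro-regions of human breast cancer tissue was profiled to compare gene expression between 3 histological site types. Pick-Seq, the approach used, lifts a spot of tissue out of a section so that its RNA can be amplified and sequenced on its own. The labels assigned 4 regions to T cell, 5 to TIL, described as holding both tumor and T cells, and 5 to Tumor. Because the regions were chosen by type, differences in T cell and epithelial markers are not independent of that choice. The labels do not tie regions to donors.

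The libraries were shallow. Total counts ranged from 67449 in T cell region 4 to 404365 in Tumor region 3, with means of 106994 ± 58060 for T cell (SD, n = 4), 162761 ± 29264 for TIL (SD, n = 5) and 197968 ± 126783 for Tumor regions (SD, n = 5). T cell regions held 3657 ± 718 detected genes, TIL regions 9612 ± 1180.0 and Tumor regions 7482 ± 2404. The exact permutation p was 0.0317 for T cell against Tumor, 0.0159 for T cell against TIL and 0.119 for TIL against Tumor, and adjusted over 21 tests these became 0.0952, 0.0833 and 0.208. After every library was thinned to 67449 counts, 3498 ± 762, 8158 ± 799 and 6500.4 ± 2066 genes were detected in the same order. Mitochondrial transcripts took 2.93% ± 1.32 of counts in T cell regions, 5.89% ± 0.52 in TIL regions and 5.65% ± 1.22 in Tumor regions.

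T cell regions were the least correlated, among themselves and with the other types. The mean Spearman correlation was 0.221 between pairs of T cell regions, 0.450 between TIL regions and 0.465 between Tumor regions. Tumor and TIL regions correlated with each other at 0.453, whereas T cell regions correlated at 0.0883 with Tumor and 0.146 with TIL regions. Across all 14 regions the mean was 0.403 within types and 0.246 between them, a difference of 0.156 with a permutation p of 0.00038. By exact one-sided permutation within pairs of types, p was 0.00794 for T cell against Tumor and for T cell against TIL (adjusted p = 0.0119 each), and 0.310 for TIL against Tumor. The first principal component, with 39.1% of variance, separated T cell regions from the rest, and Tumor regions 1 and 2 lay apart from the other Tumor regions on the second, with 10.4%.

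**Figure D1:**
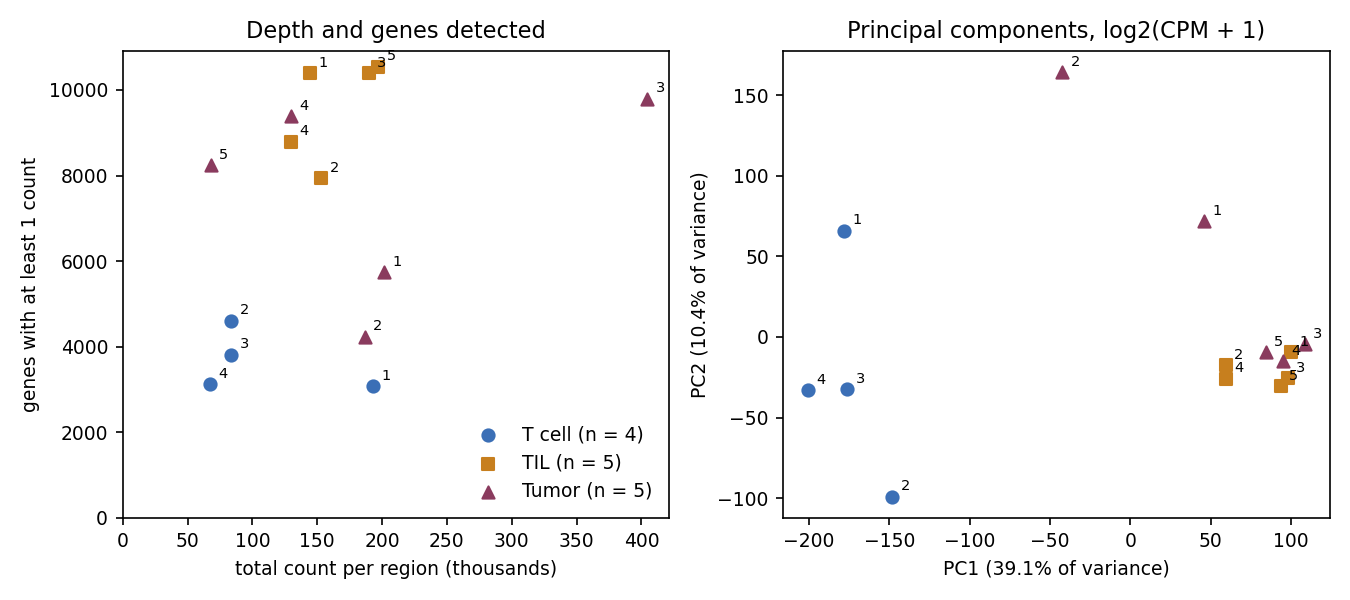
Left, genes with at least 1 count against total count for each region; right, the first 2 principal components of log2(CPM + 1), with colour and shape giving the region type and numbers the region. The T cell regions, with 3076 to 4609 detected genes, lie on one side of the first component, which holds 39.1% of variance.

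T cell regions were compared with Tumor regions to ask which transcripts set the sites labelled T cell apart from tumor sites. Luminal and epithelial transcripts were nearly absent from T cell regions. CD24, a surface glycoprotein of epithelial tumor cells (chromosome 6, 106969831 to 106975627), had 0 counts in the 4 T cell regions and 2090.3 ± 886 CPM in the 5 Tumor regions, at least 402-fold lower in T cell regions (adjusted p = 1.48e-06). GATA3, the luminal lineage transcription factor (chromosome 10, 8045378 to 8075203), measured 1.94 ± 3.87 CPM against 1176 ± 226, and its pooled ratio was 295 in favour of Tumor regions with an exact 95% interval of 81.5 to 2442 (adjusted p = 6.80e-06). ESR1, the estrogen receptor (chromosome 6, 151656691 to 152129619), had 0 counts against 590.5 ± 238 CPM, at least 119-fold lower (adjusted p = 5.80e-05). In the other direction, PDGFRB, a growth factor receptor of fibroblasts and pericytes (chromosome 5, 150113837 to 150155872), measured 788 ± 391 CPM in T cell and 17.6 ± 23.8 CPM in Tumor regions (log2 fold change 5.63, SE 1.29, adjusted p = 0.00428).

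Of 4019 genes tested with edgeR, 1022 passed an adjusted p of 0.05, 88 higher and 934 lower in T cell regions, and 663 of the lower genes had no count there. Luminal and hormone receptor genes fell in 12 of 14 tested members (13 adjusted over the list alone), with a median log2 fold change of −7.63, or −5.96 with genes without counts at their bound (camera adjusted p = 1.01e-12). Among them AGR2, a disulfide isomerase of secretory epithelium, fell from 2256 ± 1823 CPM in Tumor to 3.87 ± 7.75 CPM in T cell regions. SLC39A6, an estrogen-regulated zinc transporter, measured 3115 ± 1408 CPM in Tumor and 17.6 ± 23.8 CPM in T cell regions (log2 fold change −7.20, SE 0.92). Epithelial genes fell in 12 of 17 tested members (13 adjusted over the list alone), with a median of −6.35, or −4.98 at bounds (camera adjusted p = 3.79e-09). KRT8, KRT19, MUC1 and EPCAM, keratins and surface proteins of epithelium, were among them. KRT19 measured 5639 ± 1903 CPM in Tumor and 120.4 ± 227 CPM in T cell regions, where region 1 held 119 of 121 counts, and EPCAM was at least 71.0-fold lower. For both lists adjusted p = 0.0311 with an estimated correlation. ERBB2, the HER2 receptor, measured 62.4 ± 125 and 161 ± 91.2 CPM and did not pass (adjusted p = 0.509), and the 2 tested genes of its amplicon did not pass either. T cell region 4 held all 22 ERBB2 counts of the T cell regions. Leaving out 1 region moved the ERBB2 log2 fold change from −1.39 to as low as −7.76.

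Among the lower genes with the smallest p, GFRA1, a co-receptor for GDNF, GPRC5A, an orphan receptor, UCP2, a mitochondrial carrier, CLU, the secreted chaperone clusterin, and the long non-coding RNA LINC00993 had 0 counts in T cell regions. They were at least 237-fold, 325-fold, 233-fold, 333-fold and 162-fold lower there, with adjusted p from 6.80e-06 for GFRA1 to 2.55e-05 for CLU. CRISPLD1, a secreted protein gene, gave a pooled ratio of 530.3 in favour of Tumor regions with an exact 95% interval of 181 to 2573 (adjusted p = 3.74e-06).

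Of 22 T cell list genes only TRAC and CD3D passed the expression filter, and the others were not tested. The filter asks for a minimum count in several regions, so total counts alone did not decide this. TRAC, the constant region of the T cell receptor alpha chain (chromosome 14, 22547506 to 22552154), had 67 and 76 counts in T cell regions 2 and 4 and 0 in the others and in all Tumor regions, at least 81.9-fold higher over the group (adjusted p = 0.00485), a call that limma-voom ended. CD3D, a chain of the CD3 complex (chromosome 11, 118338954 to 118342744), was at least 22.3-fold higher (adjusted p = 0.0174), a bound that rests on T cell region 2, with 35 of 39 counts. Without that region the log2 fold change fell from 6.96 to 3.94 and the adjusted p was 0.100. Both tested genes of the T cell list rose, also when adjusted over the list alone, as did 1 of 2 cytotoxic and NK genes and 1 of 2 plasma cell genes. The other plasma cell gene went the opposite way, with 2 counts in T cell and 61 in Tumor regions. The summed T cell list held 177, 588, 0 and 164 counts in T cell regions 1 to 4, and 4 counts over all Tumor regions. The 0 of region 3 allows up to 30.9 CPM. CD52, a leukocyte surface glycoprotein, gave a ratio of 132 with an exact 95% interval of 23.1 to 5294 (adjusted p = 0.0117, or 0.0520 without T cell region 2). It was the 1 of 5 tested pan-leukocyte genes that rose, also adjusted over the list alone, and camera gave adjusted p = 0.0368 (0.140 with an estimated correlation). PTPRC and CD3E, general leukocyte and T cell markers, were too sparse to test, with 8 and 6 counts in T cell regions and 3 and 0 in Tumor regions. MS4A1, a B cell marker, had 46 counts, all in T cell region 2.

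Stromal and vascular genes were among those higher in T cell regions. Fibroblast and matrix genes took 1.87% ± 0.928 of counts in T cell (SD, n = 4) and 0.326% ± 0.271 in Tumor regions (SD, n = 5). Of 15 tested members 3 rose, PDGFRB, MMP2 and COL6A3, and 1 when adjusted over the list alone (camera adjusted p = 2.64e-12, 0.0634 with an estimated correlation). Relative log expression scaling called 9 of these genes higher and no scaling 5. COL6A3, a collagen VI chain, measured 2536 ± 1651 against 344 ± 353 CPM (adjusted p = 0.0490), and COL1A1, a collagen I chain, 1409 ± 518 against 256 ± 283 CPM (adjusted p = 0.0584). The calls of COL6A3 and of MMP2, a matrix metalloproteinase (adjusted p = 0.0319), each ended without any 1 of 6 regions, at up to 0.105 for COL6A3 without T cell region 1 and 0.0856 for MMP2 without T cell region 4. Endothelial genes rose in 1 of 3 tested members, ENG, which encodes endoglin (465 ± 410 against 30.6 ± 34.3 CPM, adjusted p = 0.0389, or 0.125 without T cell region 1), also adjusted over the list alone. Perivascular and smooth muscle genes rose in 1 of 4, MCAM, an adhesion molecule of vessel walls (adjusted p = 0.0152, or 0.0805 without T cell region 3), also adjusted over the list alone. Camera gave adjusted p = 0.00136 and 0.00693 for these 2 lists, and 0.0634 and 0.125 with an estimated correlation. The genes with the smallest p among those higher included OLFML2B, an extracellular matrix protein, ITGA5, the fibronectin receptor alpha chain, and GIMAP7, a GTPase of lymphocytes and endothelium. OLFML2B was at least 281-fold and GIMAP7 at least 158-fold higher, while ITGA5 gave a ratio of 356 with an exact 95% interval of 121 to 1729.7. SPRY1, IGFBP4, TSPAN9, TXNIP and MXRA8 also rose, with adjusted p from 0.00341 for SPRY1 to 0.00494 for MXRA8.

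Among metabolic and stress genes the calls were lower in T cell regions. Nuclear-encoded oxidative phosphorylation genes fell in 9 of 20 tested members (11 adjusted over the list alone), with camera adjusted p = 0.00117 (0.136 with an estimated correlation). COX6C, a subunit of cytochrome c oxidase, fell from 22029 ± 3968 to 1337 ± 1811 CPM (log2 fold change −4.04, SE 0.86, adjusted p = 0.00239). T cell region 1 held 1035 of 1166 COX6C counts in T cell regions, and without it the log2 fold change was −5.77. Heat shock genes fell in 4 of 8 (6 adjusted over the list alone; camera adjusted p = 0.0239, 0.140 with an estimated correlation), among them HSP90AA1 and HSPB1, chaperones, and the HSPB1 call ended without Tumor region 2 (adjusted p = 0.0536). Hypoxia and glycolysis genes fell in 2 of 10, including the lactate dehydrogenase LDHA (5 adjusted over the list alone), and macrophage genes in 4 of 8, including SPP1 and FCER1G (4 adjusted over the list alone). Proliferation genes fell in 1 of 7 (TOP2A, a DNA topoisomerase; 2 adjusted over the list alone), interferon gamma genes in 1 of 3 and immediate early genes in 1 of 8 (1 each adjusted over the list alone). The immediate early median was −1.49 while camera placed the list upward relative to other genes. Camera adjusted p for these 5 lists was 0.166, 0.166, 0.779, 0.401 and 0.783. Ribosomal protein genes fell in 4 of 28, RPL8 among them, and mitochondrially encoded genes in 3 of 12, MT-CO1 among them (3 and 4 adjusted over the list alone; camera adjusted p = 0.401 and 0.544). The median over all genes was itself −1.10, so these 2 lists lay 0.28 and 0.05 above it, and relative log expression scaling left 1 and 0 members lower. That scaling left 5 oxidative phosphorylation, 2 heat shock and 2 macrophage genes lower, and called 2 MHC class I, 2 pan-leukocyte and 2 perivascular genes higher.

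MHC class I genes, which present antigen, had no member past the threshold among 8, over all genes or adjusted over the list alone, with a median of 2.18 (camera adjusted p = 0.00094, 0.0924 with an estimated correlation). HLA-E measured 383 ± 435 CPM in T cell and 23.3 ± 36.9 CPM in Tumor regions (adjusted p = 0.0749). Of 11 type I interferon genes, 2 rose and 1 fell, with the same counts adjusted over the list alone. OAS3 and IFI27 were higher (adjusted p = 0.0218 and 0.0439) and IFIT3 lower (adjusted p = 0.0289), and the OAS3 call ended without T cell region 3 (adjusted p = 0.353), the IFIT3 call without T cell region 1 (0.0571) and the IFI27 call without any 1 of 11 regions (up to 0.118 without Tumor region 5). The list's median was 1.64 while the difference in its score was −0.15 (camera adjusted p = 0.00265, 0.0973 with an estimated correlation). As a share of counts the list took 0.414% ± 0.0425 in T cell regions (lowest 0.360%). In Tumor regions it took 0.117% ± 0.0478 (highest 0.158%), and this difference was not tested.

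None of 5 MHC class II, 3 nuclear-retained RNA and 1 naive and lymphoid chemokine genes tested passed over all genes or adjusted over the list alone (camera adjusted p = 0.121 and 0.166 for the larger lists). The MHC class II median was 0.79 and the difference in score −0.38.

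By score, epithelial genes averaged 0.84 ± 0.46 in T cell (SD, n = 4) and 7.12 ± 0.72 in Tumor regions (SD, n = 5), luminal genes 1.29 ± 1.40 and 8.87 ± 0.68, and macrophage genes 1.35 ± 0.58 and 3.66 ± 1.06. The exact two-sided permutation p was 0.0159 for each of these 3 lists, the smallest possible, and 0.0317 for the fibroblast and endothelial lists, whose scores were 2.98 and 3.08 higher in T cell regions. The T cell score differed by 2.37 with an exact p of 0.0952. No score passed after adjustment, the smallest adjusted p being 0.0615.

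The predominance of lower genes held in every setting but its extent did not. DESeq2 called 368 genes higher and 784 lower, relative log expression scaling 158 and 675, and no filter 217 and 638. With only the 2 groups in the fit 294 of 2023 tested genes passed, and after thinning 444 of 1700. With detected genes as a covariate 379 of 4019 passed. Of 44 calls on genes named here, 34 held in every fit without 1 region in which the gene was tested, and 20 in every other setting in which it was tested; TOP2A was tested in 10 of the 14 fits without 1 region. These p-values are too small if regions share a donor.

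**Figure D2:**
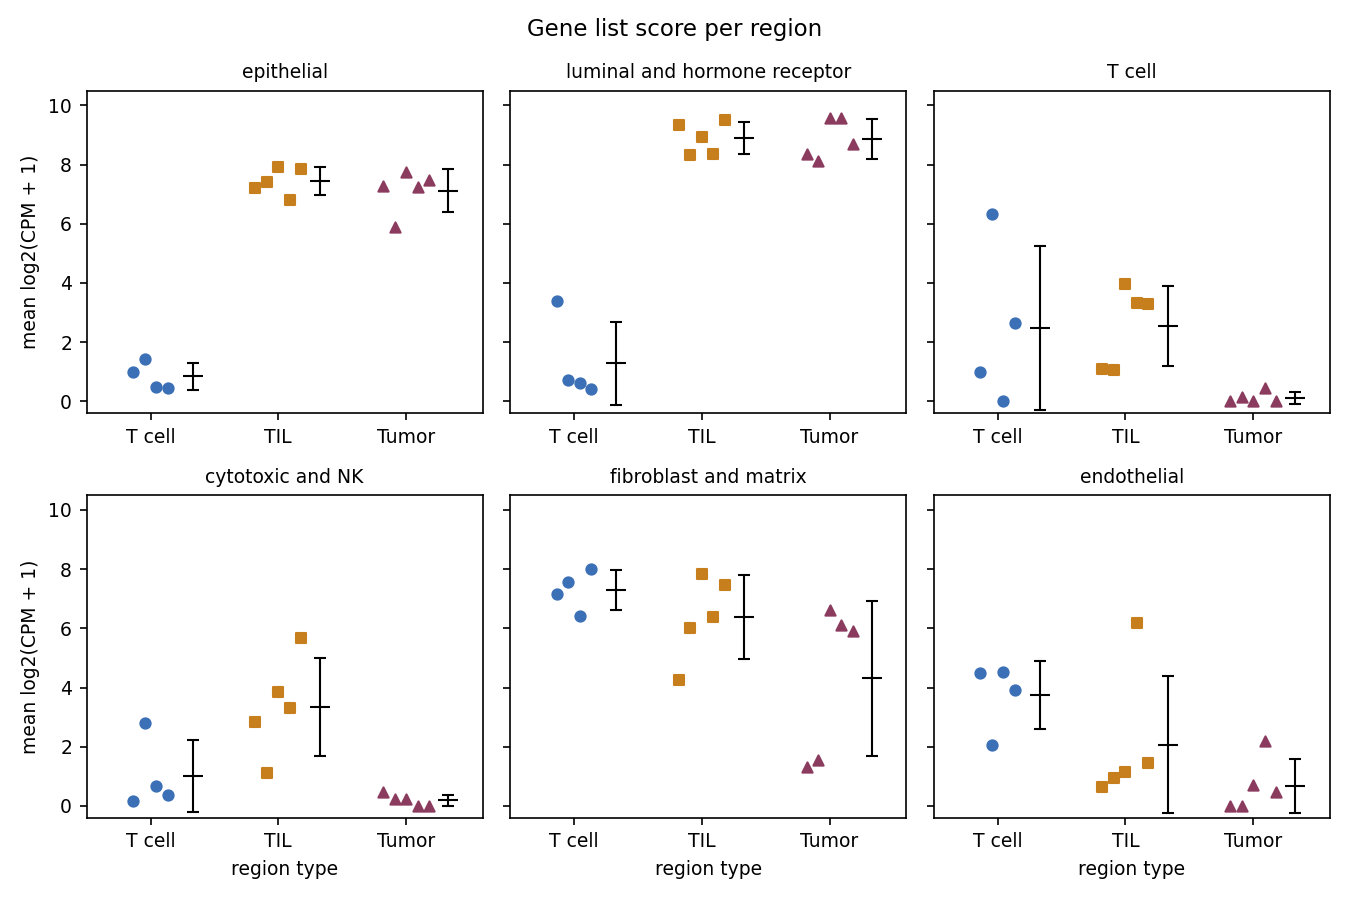
Gene list scores, the mean log2(CPM + 1) of detected members, by region type for 6 lists; points are regions and bars mean ± SD. The epithelial score averages 0.84 in T cell, 7.44 in TIL and 7.12 in Tumor regions, while the T cell score averages 2.49, 2.55 and 0.12.

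TIL regions, where the labels place tumor cells and T cells together, were compared with Tumor regions to ask what the added lymphocytes contribute. T cell list counts were 16 to 154 per TIL region and 0 to 3 per Tumor region, and epithelial transcripts were abundant in both. TRAC had counts in all 5 TIL regions (69.6 ± 46.2 CPM, SD, n = 5) and 0 in the 5 Tumor regions, at least 22.7-fold more. CD3D measured 119 ± 89.7 CPM against 0, at least 37.5-fold more, and CCL5, a chemokine of activated T and NK cells, 101 ± 52.2 CPM against 0, at least 31.4-fold more. KRT19 measured 4547 ± 2096 CPM in TIL and 5639 ± 1903 CPM in Tumor regions, and ESR1 618 ± 324 and 590.5 ± 238 CPM.

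None of 4019 genes passed an adjusted p of 0.05 with edgeR, the smallest being 0.961. An unadjusted p below 0.05 was found for 68 genes, 63 of them higher in TIL regions, fewer than the 1 in 20 that chance gives. DESeq2 called 0 of 18726 genes, with 229 below an unadjusted 0.05, and limma-voom 0 of 4019, with 241. Without the expression filter 5 genes passed, all higher in TIL regions: IGHG1, IGLC2, IGLC3 and IGLV8-61, immunoglobulin genes, and GNLY, the cytotoxic granule protein granulysin. The immunoglobulin calls rest on TIL region 4, which held 2512 of 2522 IGHG1, 956 of 957 IGLC2, 1239 of 1239 IGLC3 and 287 of 287 IGLV8-61 counts over TIL regions. Only 1.52% of simulated 4-fold changes were recovered here, so the absence of calls does not show that the types are alike.

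Both tested T cell genes passed when adjusted over the list alone, with a median log2 fold change of 6.84, or 4.87 with genes without counts at their bound. The T cell score averaged 2.55 ± 1.37 in TIL and 0.12 ± 0.19 in Tumor regions (difference 2.43, exact two-sided permutation p = 0.00794, the smallest possible). The cytotoxic and NK score averaged 3.35 ± 1.65 and 0.19 ± 0.20 (difference 3.16, exact p = 0.00794), with 1 of 2 tested genes past when adjusted over the list alone. NKG7, a cytotoxic granule membrane protein, measured 145 ± 162 CPM in TIL and 18.0 ± 40.3 CPM in Tumor regions. Tumor region 1 held all 20 NKG7 counts of the Tumor regions. Leaving out 1 region moved the NKG7 log2 fold change from 2.88 to as high as 7.42. The pan-leukocyte score was 2.68 higher (exact p = 0.0159), 2 of 5 tested genes passed adjusted over the list alone, and camera gave adjusted p = 0.0156 (0.441 with an estimated correlation). CORO1A, an actin regulator of leukocytes, gave a pooled ratio of 127 with an exact 95% interval of 22.2 to 5060.5, and CD52 75.8 with 13.1 to 3046. Over all genes no member of these 3 lists passed, and after adjustment over 93 tests no score did.

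Fibroblast and MHC class I genes were higher by camera but not by any single gene, over all genes or adjusted over the list alone. Camera gave adjusted p = 8.55e-05 for fibroblast and matrix and 0.0341 for MHC class I genes, and 0.628 for each with an estimated correlation. COL1A1 measured 929 ± 974 CPM in TIL and 256 ± 283 CPM in Tumor regions, and PDGFRB 115 ± 110 and 17.6 ± 23.8. NLRC5, a transactivator of MHC class I genes, measured 109 ± 42.0 and 14.9 ± 21.7 CPM. IFI6, an interferon-induced gene, measured 646 ± 445 and 157 ± 68.7 CPM, and MLPH, a luminal vesicle transport gene, 1808 ± 325 and 855 ± 490.2 CPM. ERBB2 measured 255 ± 138 and 161 ± 91.2 CPM. The median log2 fold change was 0.22 for epithelial and −0.06 for luminal genes, the luminal score differing by 0.02 in the other direction. Median and score also differed in sign for interferon gamma (−0.61 and 0.52), macrophage (−0.31 and 0.34), proliferation (0.16 and −0.28), heat shock (−0.14 and 0.25) and nuclear-encoded oxidative phosphorylation genes (−0.0714 and 0.0043).

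**Figure D3:**
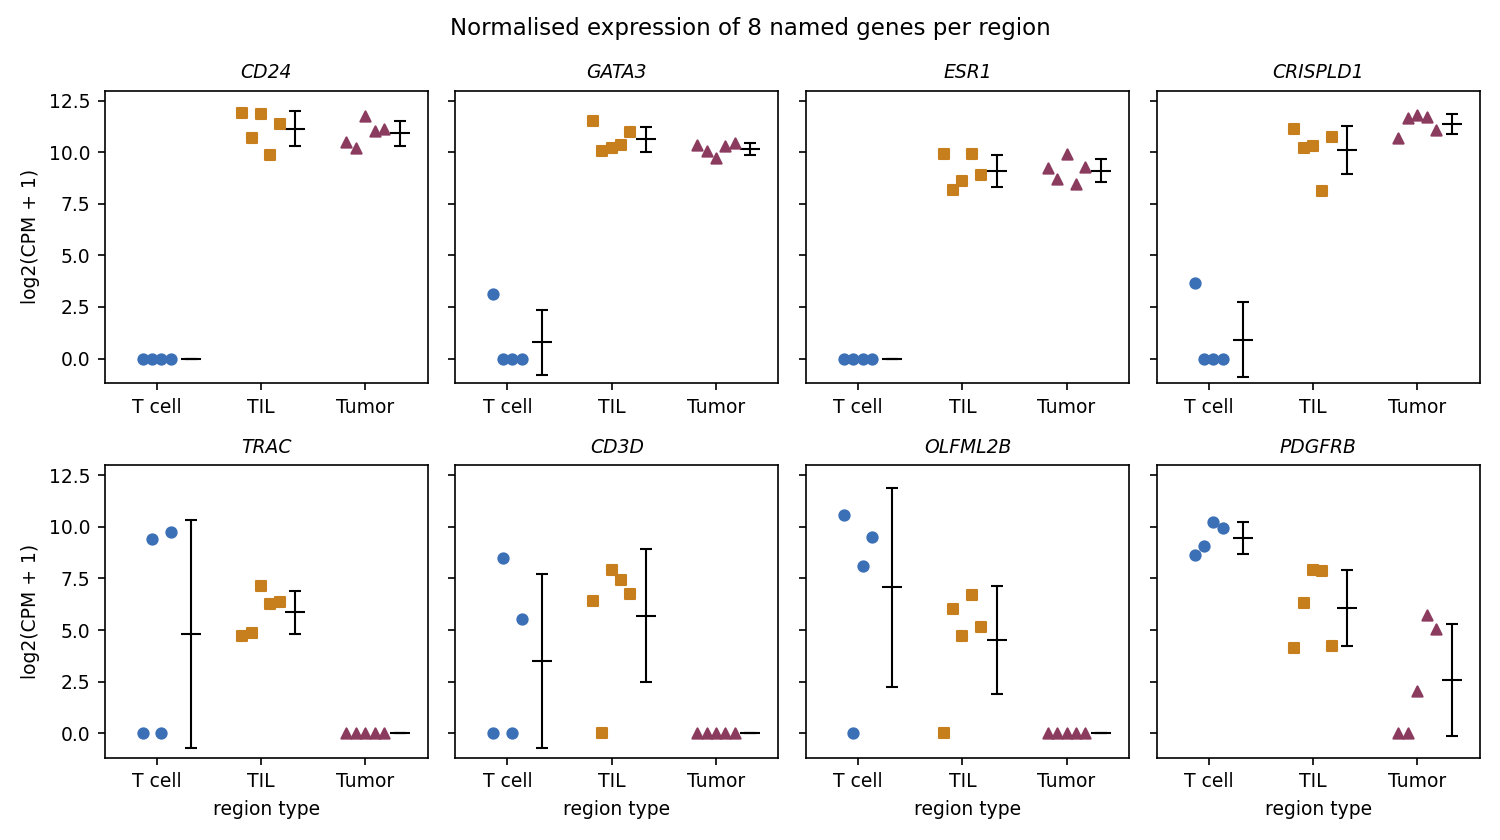
Normalised levels, log2(CPM + 1), of 8 named genes by region type; points are regions and bars mean ± SD. CD24 has no count in T cell regions and averages 2090.3 CPM in Tumor regions, and TRAC has counts in all 5 TIL regions and in none of the Tumor regions.

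T cell regions were compared with TIL regions to ask how sites labelled T cell differ from sites labelled as holding tumor and T cells. Luminal genes were lower in T cell regions. Neither TRAC nor CD3D, the only T cell list genes that passed the filter, passed the threshold, and the other list members were not tested. CD24 had 0 counts in the 4 T cell regions and 2558 ± 1265 CPM in the 5 TIL regions, at least 470.2-fold lower (adjusted p = 9.89e-07). ESR1 was at least 106-fold lower, from 618 ± 324 CPM (adjusted p = 7.35e-05), and SLC39A6 fell to 17.6 ± 23.8 CPM from 2166 ± 505 (log2 fold change −6.68, SE 0.90, adjusted p = 2.38e-05). TRAC measured 385 ± 451 CPM in T cell and 69.6 ± 46.2 CPM in TIL regions (adjusted p = 0.285). UACA, an apoptosis-related protein of the cytoskeleton, rose to 902 ± 386 CPM in T cell from 51.5 ± 56.2 CPM in TIL regions (log2 fold change 4.12, SE 1.23, adjusted p = 0.0191).

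Of 4019 genes, 961 passed with edgeR, 7 higher and 954 lower in T cell regions, and 689 of the lower genes had no count there. Luminal genes fell in 13 of 14 tested members (13 adjusted over the list alone), with a median of −7.44, or −6.19 at bounds (camera adjusted p = 8.57e-15, 0.0172 with an estimated correlation). Epithelial genes fell in 13 of 17 (13 adjusted over the list alone), with a median of −6.78, or −5.17 at bounds (camera adjusted p = 2.18e-10, 0.0226 with an estimated correlation). GPRC5A, LINC00993, GFRA1 and UCP2 had 0 counts in T cell regions and were at least 233-fold, 185-fold, 145-fold and 250.1-fold lower. CRISPLD1 gave a pooled ratio of 245 in favour of TIL regions with an exact 95% interval of 83.6 to 1190.1. KRT8, KRT19, MUC1, CLDN4, a tight junction protein, and AGR2 also fell, with adjusted p from 2.78e-05 for AGR2 to 0.00145 for KRT19. ERBB2 measured 62.4 ± 125 CPM in T cell and 255 ± 138 CPM in TIL regions (adjusted p = 0.345). All its counts in T cell regions were in region 4, and leaving out 1 region moved the log2 fold change from −2.05 to as low as −8.35.

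Besides UACA, the genes that rose were ITGA5, TMEM204, an endothelial membrane protein, TNFRSF14, a lymphocyte co-receptor, OLFML2B, SPRY1, a receptor kinase signalling inhibitor, and METTL16, an RNA methyltransferase. Their adjusted p ran from 0.0173 for ITGA5 to 0.0453 for METTL16. Leaving out 1 region ended each of these calls but that of UACA, which ended without the filter (adjusted p = 0.0605) and with detected genes as a covariate (0.384): ITGA5 without T cell region 3 (0.0522), TMEM204 without T cell region 2 (0.0651), and TNFRSF14, OLFML2B, SPRY1 and METTL16 without any 1 of 7, 6, 6 and 10 regions. With detected genes as a covariate the OLFML2B fold change turned to −4.15.

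Fibroblast, endothelial and perivascular genes were higher by camera (adjusted p = 2.31e-09, 0.00407 and 0.00562), but 0 of 15, 0 of 3 and 0 of 4 members passed over all genes or adjusted over the list alone, and adjusted p = 0.129 for each with an estimated correlation. PDGFRB measured 788 ± 391 CPM in T cell and 115 ± 110 CPM in TIL regions (adjusted p = 0.0739). The T cell score averaged 2.49 ± 2.78 in T cell and 2.55 ± 1.37 in TIL regions (exact two-sided permutation p = 0.968), with 0 of 2 tested genes past and a median log2 fold change of 1.09. As a share of counts the list took 0.259% ± 0.312 in T cell and 0.0451% ± 0.035 in TIL regions, and this difference was not tested. The cytotoxic and NK score was 2.35 lower in T cell regions (exact p = 0.0317). As a share of counts that list took 0.0589% ± 0.0682 in T cell and 0.0772% ± 0.0730 in TIL regions, which was not tested. Oxidative phosphorylation genes fell in 9 of 20 (10 adjusted over the list alone; camera adjusted p = 0.00562, 0.202 with an estimated correlation), COX6C and UQCRFS1, respiratory chain subunits, among them. Heat shock genes fell in 4 of 8 (5 adjusted over the list alone; camera adjusted p = 0.0425, 0.202 with an estimated correlation), and hypoxia and glycolysis genes in 4 of 10 (5 adjusted over the list alone; camera adjusted p = 0.146), LDHA and VEGFA, an angiogenic factor, among them. Macrophage genes fell in 2 of 8, SPP1 and FCER1G (2 adjusted over the list alone; camera adjusted p = 0.421), and proliferation genes in 2 of 7 (2 adjusted over the list alone; camera adjusted p = 0.644). Interferon gamma genes fell in 1 of 3 (2 adjusted over the list alone) and immediate early genes in 1 of 8 (0 adjusted over the list alone), with camera adjusted p = 0.585 and 0.982. Ribosomal protein genes fell in 4 of 28 and mitochondrially encoded genes in 3 of 12 (3 and 5 adjusted over the list alone; camera adjusted p = 0.201 and 0.438), and relative log expression scaling left 0 of each. That scaling left 4 oxidative phosphorylation, 1 heat shock and 1 hypoxia and glycolysis gene lower, and 0 proliferation, interferon gamma, immediate early and type I interferon genes, and called 2 fibroblast and 1 endothelial gene higher.

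MHC class I genes had a median of 0.34 and 0 of 8 members past, with camera adjusted p = 0.00981 (0.202 with an estimated correlation), while their score was 0.83 lower in T cell regions. They took 0.617% ± 0.161 of counts in T cell and 0.310% ± 0.145 in TIL regions, the direction opposite to the score, which was not tested. Type I interferon genes had a median of −0.14 and 1 of 11 lower (0 adjusted over the list alone), and camera placed them higher relative to other genes (adjusted p = 0.0143, 0.202 with an estimated correlation), while their score was 1.38 lower in T cell regions (exact two-sided permutation p = 0.0159, the smallest possible; adjusted p = 0.0615). Their share of counts was 0.414% ± 0.0425 in T cell and 0.225% ± 0.134 in TIL regions, the opposite direction. Median and score also differed in sign for naive and lymphoid chemokine (1.52 and −0.38) and nuclear-retained RNA genes (0.18 and −0.0636). Pan-leukocyte genes had 0 of 5 past, a median of −0.52 and a camera direction upward (adjusted p = 0.417).

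DESeq2 called 105 genes higher and 598 lower, voom 27 and 548, relative log expression scaling 50 and 530, and no filter 66 and 510. With only the 2 groups 370 of 2526 tested genes passed, after thinning 354 of 1700, and with detected genes as a covariate 38 of 4019. Detected genes ran from 3076 to 4609 in T cell and from 7937 to 10543 in TIL regions. The ranges do not overlap, so this covariate cannot be told apart from region type. Of 30 calls on genes named here, 24 held in every fit without 1 region in which the gene was tested, and 11 in every other setting in which it was tested. VEGFA was tested in only 6 of the 14 fits without 1 region. These p-values, too, are too small if regions share a donor.

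Of the 1022 genes that separated T cell from Tumor regions, 611 (59.8%) had their TIL level between the other types and 974 (95.3%) were nearer to Tumor, most of them among the 934 lower genes. The genes were selected with the same Tumor and T cell regions, and no value for unchanged TIL regions was computed. On a scale from 0 at Tumor to 1 at T cell, the median TIL position was 0.0166 for genes lower in T cell regions and 0.523 for genes higher there. No gene set TIL regions apart from both other types, and 5 did without the filter.

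Gene lists of regulatory and checkpoint, B cell, dendritic, mast cell and neutrophil, adipocyte, basal epithelial and erythrocyte genes had no member that passed the filter. None of their genes was tested in any comparison.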

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

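The splits of regions into groups were fixed before the data were examined, and the 8 explanation tests for the patterns below were written after the results were seen. Of 100 splits of the regions into groups of the real sizes, only the real one (1 of 100) gave at least 1022 genes for T cell against Tumor, the highest other giving 532, and only the real one (1 of 100) gave 961 for T cell against TIL, the highest other giving 6. For TIL against Tumor, 100 of 100 splits gave at least the 0 genes of the real grouping, which carries no information because no split can give fewer.

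T cell list counts differed between T cell regions, with 177, 588, 0 and 164 in regions 1 to 4, or 0.0916% (exact 95% interval 0.0786 to 0.106), 0.703% (0.647 to 0.762), 0% (0 to 0.00442) and 0.243% (0.207 to 0.283) of counts. Depth does not account for it, since the share of region 2 predicts 587 counts in region 3 and 0 were seen. A swapped label between T cell and Tumor regions is ruled out, as the highest epithelial share in a T cell region was 0.114% (exact 95% interval 0.0919 to 0.139) and the lowest in a Tumor region 1.17% (1.09 to 1.25). Few captured molecules per region could contribute, as 2.25 of 28 ribosomal protein genes had no count per T cell region on average, where counting error predicts 0.159. Whether region 3 holds few T cells was not tested, and GZMA, a cytotoxic granule enzyme looked at after its values were seen, had 76 counts there, 783 CPM and the highest of any region.

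More genes were lower than higher in T cell against Tumor regions. TMM scaling is not the whole cause, since at least 81.0% of calls were lower under the other 2 scalings, and neither is depth, since 84.9% were lower after thinning. The expression filter was not among the explanations tested. Without it 217 genes were higher and 638 lower, against 88 and 934 with it, so the extent of the pattern depended on the filter. Fewer genes captured in T cell regions whatever the tissue may contribute, but the test made cannot decide it. Of 48 ribosomal protein and oxidative phosphorylation genes, 21.9% had no count per T cell region, against 1.25% per TIL and Tumor region. Some oxidative phosphorylation genes were themselves among the lower calls, so they are part of the pattern. Ribosomal protein genes alone had 2.25 of 28 without a count per T cell region, against 0 per TIL and Tumor region.

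Immunoglobulin counts were high in TIL region 4, where IGHG1 took 1.94% of counts (exact 95% interval 1.86 to 2.01). Cross-over from another of the 14 libraries is ruled out, as the largest IGHG1 count among them was 9 against 2512, while libraries outside them were not examined. Plasma cells in the region could be the source, as the other plasma cell genes had 31 counts there, 262 CPM against at most 139.7 CPM in other TIL and 161 CPM in Tumor regions.

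By a Dixon test within each region type, 11 of 78 groups of values held an extreme region, where chance gives about 1 in 20, or 3.9. The B cell score was 4.32 in T cell region 2, the others lying between 0 and 0.67. The macrophage score was 2.21 in T cell region 1 (others 0.98 to 1.16). The luminal score was 3.38 in T cell region 1 (others 0.43 to 0.73). The immediate early score was 0.97 in T cell region 2 (others 2.34 to 2.598). Total counts were 193332 in T cell region 1 (others 67449 to 83675). The plasma cell score was 6.07 in TIL region 4 (others 0.33 to 1.45). The endothelial score was 6.17 in TIL region 4 (others 0.64 to 1.45). In Tumor region 4 the pan-leukocyte score was 3.95 (others 1.62 to 1.83) and the macrophage score 5.49 (others 2.82 to 3.53). In Tumor region 2 the epithelial score was 5.89 (others 7.25 to 7.74) and MALAT1 took 6.59% of counts (exact 95% interval 6.48 to 6.71; others 0.576% to 1.69%).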

How the results depend on the processing

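All settings but the removal of Tumor regions 1 and 2, chosen after the results were seen, were fixed before the data were examined. The cause of the differences between settings was not tested.

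The settings also differed in how many genes they tested, so numbers of calls are not directly comparable. For T cell against Tumor, 1022 of 4019 genes passed. With only the 2 groups in the fit 294 of 2023 passed, and after thinning 444 of 1700. With the region number as a block 613 of 4019 passed, and with detected genes as a covariate 379 of 4019. Leaving out each region gave 754 to 1455, in fits of 3679 and 5042 genes. For T cell against TIL, 961 of 4019 passed. Of the same 4019 genes, 575 passed with limma-voom, 580 with relative log expression scaling, 610 with the block and 38 with the covariate. Without the filter 576 of 20057 passed, with only the 2 groups 370 of 2526 and after thinning 354 of 1700. The covariate cannot be told apart from region type there, as detected genes did not overlap between T cell and TIL regions. Leaving out each region gave 744 to 1341, in fits of 3665 and 5042 genes. For TIL against Tumor 0 genes passed in every setting but without the filter, where 5 did, and 5 genes then also set TIL apart from both other types.

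The labels do not say that region numbers pair regions across types, so the block has no known meaning. The 13 same-number pairs correlated at −0.0323 to 0.0664, with a mean of 0.0092 against −0.0022 for other pairs. Of 14 regions, 7 correlated best with a region of their own number, and the number that chance gives was not computed. Between TIL and Tumor regions the same-number pairs gave 0.0664, 0.0268, 0.0643, −0.0114 and 0.0356 for numbers 1 to 5. The mean of 0.0092 pools these with same-number pairs that include a T cell region, which ran from −0.0323 to 0.00903. Whether some numbers mark a shared section or donor was not tested.

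The share of genes with TIL between the other types was 59.8%. It was 83.3% with DESeq2, 74.7% with limma-voom, 80.2% with relative log expression scaling, 67.8% without scaling and 71.7% without the filter. It was 68.4% with only the 2 groups, 70.0% with the block, 54.1% with the covariate and 68.9% after thinning. Leaving out each region gave 58.6% to 70.2%.

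Camera called 10 lists for T cell against Tumor, 2 with an estimated correlation, 20 without the filter, and 8 to 14 leaving out each region. For TIL against Tumor it called 3 lists, 0 with an estimated correlation, 6 without the filter and 1 to 5 leaving out each region. Fry, which asks whether a list changed at all and not relative to other genes, called 0 lists directional and 0 mixed there. For T cell against TIL camera called 9 lists, 2 with an estimated correlation, and 6 to 12 leaving out each region.

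The T cell score difference between T cell and TIL regions, −0.06, turned to 0.29 with a pseudocount of 10 and 0.12 without TMM scaling, and ran from −1.34 to 0.77 leaving out each region. The ribosomal protein score difference between TIL and Tumor regions, 0.37, turned to −0.714 percentage points as a share of members with a count after thinning.

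The ESR1 log2 fold change of TIL against Tumor, 0.06, was −0.23 with DESeq2, −0.0292 with limma-voom, −0.23 with relative log expression scaling and −0.0444 without scaling. It was −0.0185 with the block, −0.15 with the covariate, −0.0527 after thinning and −0.0184 without Tumor regions 1 and 2, and ran from −0.22 to 0.30 leaving out each region. That of KRT19 was 0.0328 with the covariate and −0.31 before. That of OLFML2B for T cell against TIL was −4.15 with the covariate and 3.82 before.

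The difference in detected genes between T cell and Tumor regions ran from −4636 to −3245 leaving out each region, with an exact permutation p of up to 0.0714, and between TIL and Tumor regions from 1318.8 to 2709.3. Without TIL region 2 the latter was 2548.7 with an exact permutation p of 0.0476. The similarity difference ran from 0.146 to 0.171 with a permutation p of up to 0.0017. Of 2477 alternative values for 95 results on named genes, 2262 kept direction and call, 178 were weaker, 24 stronger and 13 reversed.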

Other observations

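The genes below were chosen after their values were seen, and the values given here carry no test. CGA, the glycoprotein hormone alpha chain, measured 13645 ± 12431 CPM in Tumor (SD, n = 5), 7070 ± 5709 CPM in TIL (SD, n = 5) and 6.78 ± 13.6 CPM in T cell regions (SD, n = 4). Among Tumor regions CGA ranged from 219 CPM in region 2 to 27258 CPM in region 5.

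COL4A2, a collagen IV chain, measured 2442 ± 1616 CPM in T cell, 371 ± 596 CPM in TIL and 182 ± 219.7 CPM in Tumor regions. COL4A1, its partner chain, measured 1232 ± 1503, 321 ± 468 and 106 ± 118 CPM, with 429 and 308 counts in T cell regions 1 and 3 but 0 and 8 in regions 2 and 4. SPARC, a matrix glycoprotein, measured 3536 ± 762, 1293 ± 1146 and 808 ± 402 CPM, and IGFBP7, a vascular matrix protein, 3247 ± 802, 816 ± 973 and 372 ± 437 CPM.

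IL7R, the receptor of a T cell survival cytokine, had 129 counts in T cell region 2, 66 in T cell region 4, 16 in TIL region 4, 2 in TIL region 5 and none elsewhere. TRBC1 and TRBC2, constant regions of the T cell receptor beta chain, had 81 and 96 counts in T cell region 1. T cell region 2 held 78 and 39, region 3 held 0 of each and region 4 held 0 and 1. Over all TIL regions they had 4 and 29 counts, and over all Tumor regions 0 each. CD8A, a chain of the cytotoxic T cell co-receptor, had 57 counts in T cell region 2, 2, 4, 18 and 26 in TIL regions 1, 2, 3 and 5, 3 in Tumor region 3 and none elsewhere. GNLY had 25, 39 and 203 counts in TIL regions 3, 4 and 5 and none elsewhere. XCL1, a lymphocyte chemokine, had 50 and 29 counts in TIL regions 3 and 5, and TPSAB1, a mast cell tryptase, 15, 27 and 24 counts in TIL regions 1, 2 and 4, with none elsewhere.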
